A study of Oryza sativa with 3 samples.

How the data were processed

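The series profiled 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine, in genomic DNA of young rice panicles 3 to 4 mm long. There was 1 library for each of 3 cultivars: 93-11, PA64s and LYP9. LYP9 is the commercial hybrid bred from PA64s as seed parent and 93-11 as pollen parent, which makes the comparison one of a hybrid with its parents. Per the labels' protocols, DNA was sheared to 200 to 300 bp, a β-glucosyltransferase placed an azide-bearing glucose on 5hmC, biotin was attached by click chemistry and the tagged fragments were collected on streptavidin beads. The labels also name an anti-5hmC antibody, which the same protocols describe for dot blots.

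Reads were mapped with BWA 0.5.8, per the submitters' processing notes. Peaks were called for each library on its own with MACS 2.0.9, per the file headers. The headers give a tag size of 81 bp, an effective genome size of 390 Mb, a q-value cutoff of 0.01, a regional background range of 10000 bp, at most 2 tags per position and no control file, and the names of the input alignments describe them as uniquely mapped and non-redundant. The headers count 10007148 tags for 93-11, 10078296 for LYP9 and 11948210 for PA64s, and they give the fragment length used for extension, MACS's d, as 83, 81 and 81 bp. The genome build is not given in the sources used here. Chromosomes are numbered 1 to 12 in the files beside a chloroplast and a mitochondrial sequence, and all coordinates below are those of the files, counted from 1.

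The deposited values are the authors' peak positions with 4 values per peak. The pileup is a coverage signal, the number of extended tags at the summit, as deposited by the authors. The pileups are whole numbers and no control was given to scale them to, so they were read as unscaled for the total number of tags. The fold enrichment is the deposited ratio of that pileup to MACS's background in the same library. The −log10 p and −log10 q of each peak are deposited as MACS wrote them. All 4 values belong to the authors and the −log10 p served as the peak score. They were used to describe, rank or filter peaks. Where pileups, folds, backgrounds or score classes of different lists are set side by side, or a minimum is common to the lists, the values are not adjusted for the different numbers of tags. Without a control library, a region that attracts tags for any reason, such as extra copies or mapping, is listed in the same way as one enriched for 5hmC. Removal of redundant reads can also limit the height a pileup can reach. The number of tags sets the depth behind each list, and the intervals below cover counting error only.

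Peaks of different lists were called shared where they overlapped by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals. Chance sharing was measured by 1000 shuffles of a list's peaks to random places on the same sequence, up to the last peak end of any list on it, without overlaps within the list; the one-sided p is the share of shuffles that reached the observed value, 0.001 at the smallest, with Benjamini-Hochberg adjustment over the 6 ordered pairs. Fisher's exact test compared how often peaks of 1 parent alone recurred in LYP9. The score of shared peaks was compared with that of peaks in 1 list only by a two-sided permutation test of the difference of medians with 100000 resamples, for which the smallest p is 1e-05, adjusted over the 3 lists. Peaks are not biological replicates. With 1 library per cultivar, every p-value here concerns the positions or scores of peaks in these libraries, and none tests a difference between cultivars.

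The rule for naming regions was fixed before the data were examined. It names the 10 regions present in all 3 lists with the highest mean within-list percentile of the score and the 5 highest-scoring peaks found in each list alone. The rule would have named genes, but the gene table at hand is of the assembly ASM3414082v1 and was not joined to coordinates of an unnamed build. For the same reason the planned comparisons with gene features, transposon-related genes, other gene lists, base composition and gene density were not run, and regions are named by position instead. Counts in 1 Mb windows with their shuffles, the 200 kb stretches and the first 8 Mb of chromosomes 4 and 10 were chosen after the values were seen.

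Alternatives chosen beforehand changed the rule for sharing to a 50% overlap of both peaks or a distance of up to 500 bp. Others took a −log10 p at or above the median of the pooled lists, 15.35, lists cut to equal length or shuffles within 1 Mb. The rest were merging of peaks within 500 bp, a score adjusted for peak length by rank regression and each sequence left out in turn. Leaving out both organelle sequences was chosen beforehand for peak numbers only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. The routines were tested on simulated data. Among 40 pairs of unrelated lists with the peak lengths of 93-11 and PA64s, 2 reached p of 0.05. These lists were placed by the same random shuffle, so this checks the code and not the fit of the shuffles to clumped peaks. Planted sharing of 40% in a list of 2545 peaks came back as 40.2%, and a planted score shift of 10 came back as 9.85.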

Results

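The data consist of 3 lists of peaks in 5hmC capture libraries from young panicles, 1 for each of the rice cultivars 93-11, PA64s and LYP9. Without a control, enrichment for 5hmC at single peaks was not established. 93-11 is an indica line and PA64s a male-sterile line used as seed parent. The libraries behind the lists held 10007148 tags for 93-11, 10078296 for LYP9 and 11948210 for PA64s. There were no replicates, so differences between cultivars have no replicate check.

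The parent 93-11 had the most peaks, PA64s the fewest, and the hybrid lay between them. The lists held 4077 peaks in 93-11, 3628 in LYP9 and 2545 in PA64s, although the PA64s library held the most tags. 93-11 thus had 1.60 times as many peaks as PA64s with 0.838 times as many tags. The peaks covered 593.0 kb in 93-11, 519.1 kb in LYP9 and 379.6 kb in PA64s. Nuclear chromosomes carried 3970, 3489 and 2396 of these peaks in the same order. Mitochondrial peaks ran the other way, with 105 in 93-11, 114 in LYP9 and 121 in PA64s. On the chloroplast sequence, 93-11 had 2 peaks, LYP9 25 and PA64s 28.

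Peaks were narrow in every list. The median length was 109 bp in 93-11, 106 bp in LYP9 and 109 bp in PA64s. Peaks of 200 bp or longer, the lower end of the sheared fragment size, made up 15.01%, 14.7% and 15.8% of the lists. Tags were extended to MACS's d of 81 to 83 bp, so peak length does not measure fragment length directly. The median fold enrichment over MACS's background, as the authors' peak caller gave it, was 8.47 in 93-11, 8.92 in LYP9 and 8.06 in PA64s. The mitochondrial peaks stood on a high background. Their median fold was 3.35 in 93-11, 3.63 in LYP9 and 3.41 in PA64s, at median pileups of 89, 83.5 and 132 tags. The 2 chloroplast peaks of 93-11 had a median fold of 25.1, against 18.2 for those of LYP9 and 24.5 for those of PA64s.

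The distribution along the chromosomes was uneven in the 3 lists. Chromosome 10 had the highest nuclear density, with 18.0 peaks per Mb in 93-11, 16.6 in LYP9 and 12.8 in PA64s. Chromosome 2 had 6.12, 4.98 and 2.70 peaks per Mb, and chromosome 3 had 6.07, 5.05 and 4.04. The densest window of 1 Mb was the same in every list. It lay between 5 and 6 Mb of chromosome 10 and held 104 peaks in 93-11, 107 in LYP9 and 99 in PA64s. The median window held 7 peaks in 93-11, 6 in LYP9 and 3 in PA64s. The densest window of any shuffled set held 36, 36 and 30 peaks, so that the observed maximum was beyond all 1000 shuffles of each list (one-sided permutation p = 0.001, the smallest possible). Other dense windows lay at 9 to 10 Mb of chromosome 7, with 95, 86 and 72 peaks, and at 2 to 3 Mb of chromosome 4, with 96, 91 and 59. A window at 13 to 14 Mb of chromosome 3 held 78, 73 and 59 peaks on an otherwise sparse chromosome. The 37 densest of the 377 windows held 38.4% of nuclear peaks in 93-11, 40.4% in LYP9 and 46.5% in PA64s.

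**Figure D1:**
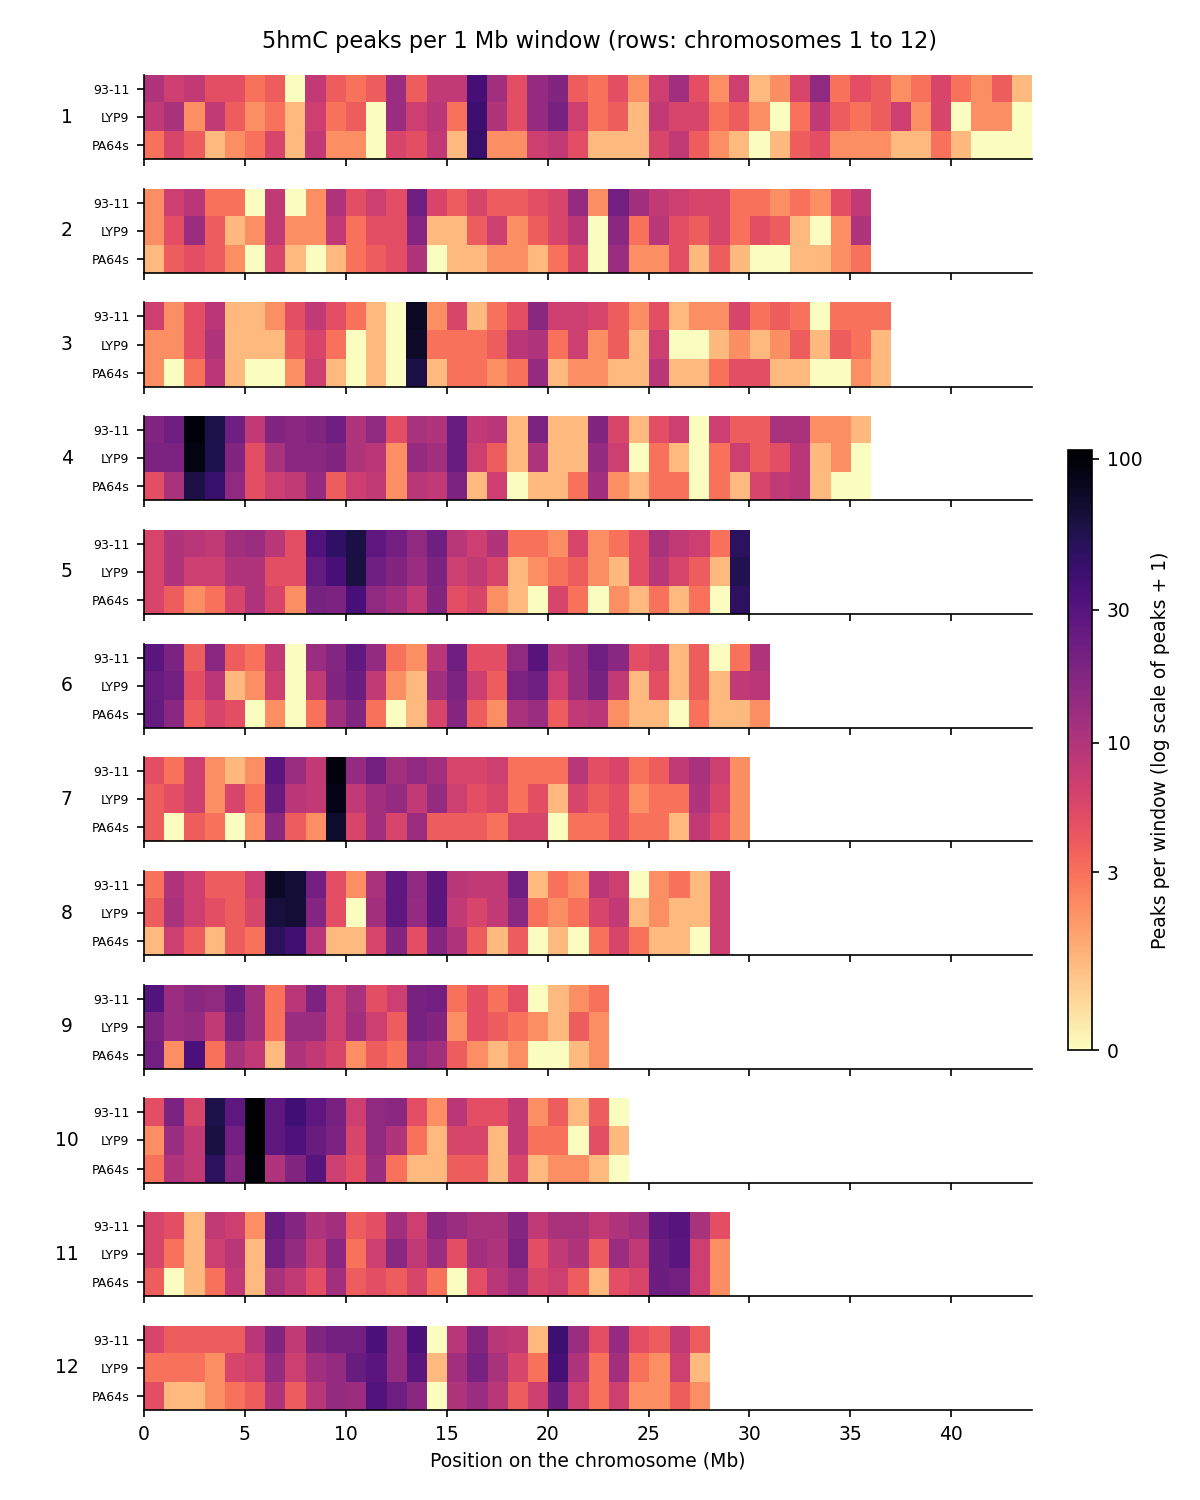
Number of peaks per 1 Mb window on the 12 nuclear chromosomes; the horizontal axis is position in Mb, each chromosome has a row for each cultivar, and colour gives the peak number on a log scale. The window at 5 to 6 Mb of chromosome 10 is the darkest in all 3 lists, with 104, 107 and 99 peaks in 93-11, LYP9 and PA64s.

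Peaks gathered in the first 8 Mb of chromosomes 4 and 10, whose short arms are known as largely heterochromatic. On chromosome 4 this part carried 32.1 peaks per Mb in 93-11 against 8.61 on the rest of the chromosome. The densities were 29.4 against 6.83 in LYP9 and 19 against 4.91 in PA64s. On chromosome 10 they were 35.6 against 8.61 in 93-11, 34 against 7.35 in LYP9 and 26.8 against 5.36 in PA64s.

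The next comparison asked how far the lists held peaks at the same places. Peaks recurred between lists far more often than random placement gives. Without a control library, places that attract tags for any reason, such as extra copies or mapping, could recur in the same way. The shuffles do not allow for such places, so whether enrichment for hydroxymethylcytosine itself recurred was not tested. Of the 93-11 peaks, 63.7% (95% interval 62.2 to 65.2) were found in LYP9 and 40.5% (39.0 to 42.0) in PA64s. Of the LYP9 peaks, 71.8% (70.3 to 73.2) were found in 93-11 and 47.4% (45.7 to 49.0) in PA64s. Of the PA64s peaks, 65.3% (63.4 to 67.2) were found in 93-11 and 67.7% (65.8 to 69.5) in LYP9. Shuffled peaks were shared in 0.581% to 0.983% of cases on average, and no shuffle came near the observed share (one-sided permutation test, adjusted p = 0.001 for each of the 6 ordered pairs, the smallest possible). Because the lists differ in length, these shares also depend on how many peaks each list holds. When each list was limited to its 2545 highest-scoring peaks, 77.0% of the 93-11 peaks were found in LYP9 and 55.1% in PA64s. Of the PA64s peaks, 59.3% were then found in LYP9. The PA64s list holds 2545 peaks, so it kept its weak peaks while the other lists lost theirs. These shares therefore do not show which lists are more alike.

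**Figure D2:**
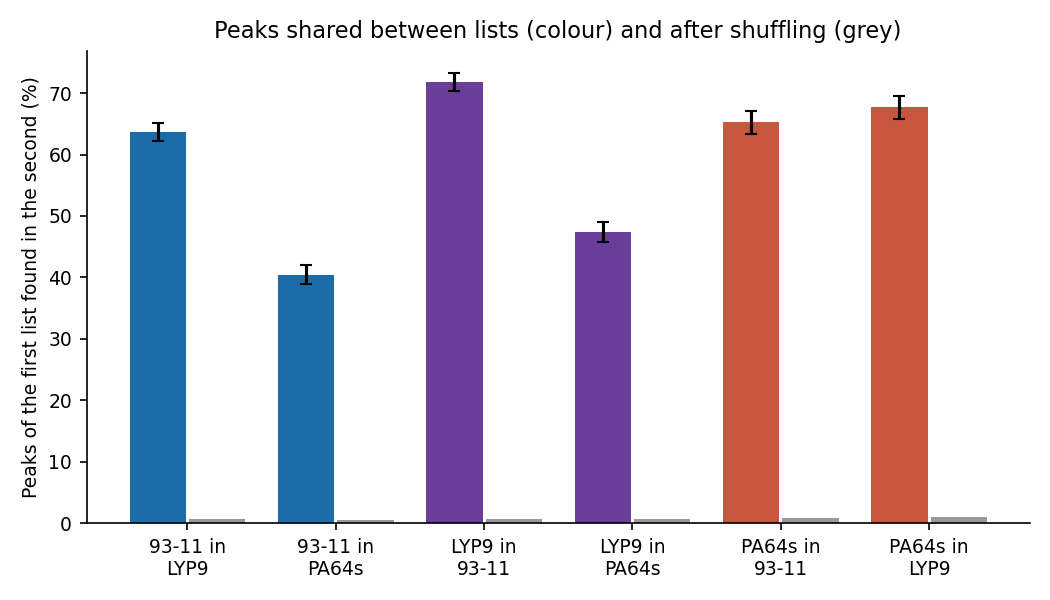
Percent of the peaks of the first-named list that overlap a peak of the second (coloured bars, with exact 95% binomial intervals) and the mean of 1000 shuffles of the same peaks (grey bars). Observed shares lie between 40.5% and 71.8%, and shuffled means between 0.581% and 0.983%.

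Merging overlapping peaks of the 3 lists gave 5740 regions, of which 1497 (26.1%) were present in all 3 cultivars. A further 1067 regions were present in 93-11 and LYP9 without PA64s, 196 in LYP9 and PA64s without 93-11, and 131 in both parents without the hybrid. Regions in a single list numbered 1348 for 93-11, 820 for LYP9 and 681 for PA64s. Shared peaks were the stronger ones in each list. In 93-11 the median −log10 p was 20.1 for peaks found in another list and 9.51 for the rest. The medians were 18.5 and 9.03 in LYP9 and 19.3 and 9.72 in PA64s (two-sided permutation test over peaks, adjusted p = 1e-05 in each list, the smallest possible). In the same lists the median pileup of shared peaks was 30, 28 and 31 tags, against 17, 16 and 19 for peaks found in 1 list only. Peaks near the cutoff of 1 list can easily miss it in another. Such differences would thus arise between like cultivars too.

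The 10 strongest regions common to the 3 lists lay on chromosomes 2, 3, 6, 9, 11 and 12 and on the mitochondrial sequence. No gene annotation of the build was used, so what these regions contain is not stated. The first was a 180 bp region of chromosome 3, from 28639272 to 28639451, with pileups of 165 tags in 93-11, 159 in LYP9 and 160 in PA64s. If 1 tag was kept per position and strand, pileups have a ceiling of 2 times MACS's d, which is 166, 162 and 162 tags. The regions of chromosomes 2, 3 and 6 named here lay at over 90% of it in each list, which held 4, 4 and 14 such peaks in total, so order and likeness among the highest pileups are limited by it. A region close to the start of chromosome 6, from 31160 to 31426, reached 150, 149 and 154 tags. A region of chromosome 11, from 27809517 to 27809831, had fold enrichments of 53.5, 51.0 and 48.4. Neighbouring regions of chromosome 2, from 28714901 to 28715049 and from 28715603 to 28715914, reached 162, 162 and 160 tags and 161, 149 and 159 tags. On chromosome 9, the region from 4730582 to 4730732 reached 90, 85 and 121 tags, and on chromosome 12 the region from 20499923 to 20500189 reached 91, 89 and 126. The mitochondrial regions began at 64902, 86867 and 273137 and reached 97, 107 and 85 tags in 93-11, 89, 100 and 87 in LYP9, and 117, 134 and 125 in PA64s.

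The scores of peaks in 1 list only are given for each list by itself. The 5 strongest 93-11-only peaks lay on chromosomes 2, 4, 7 and 12. Among them, those on chromosome 2 from 23141739 to 23141870 and on chromosome 7 from 6526287 to 6526553 each had a fold enrichment of 20.7 and a −log10 p of 42.2. The others began at 20511101 of chromosome 12, 9655681 of chromosome 7 and 2635014 of chromosome 4, with −log10 p of 38.3, 35.7 and 29.9. Their fold enrichments were 6.74, 18.3 and 6. The 5 strongest LYP9-only peaks began at 3184182 of chromosome 4, 9883540 of chromosome 6, 9377979 of chromosome 2, 10464160 of chromosome 5 and 5115610 of chromosome 10. Their −log10 p ranged from 21.5 to 24.3 and their fold enrichments from 5.6 to 13.4. When peaks within 500 bp counted as shared, those at 3184182 of chromosome 4 and 5115610 of chromosome 10 were no longer in LYP9 alone, nor was the 93-11 peak at 2635014 of chromosome 4. Fold enrichments of the 5 strongest PA64s-only peaks ranged from 15.9 to 23.8. In PA64s the strongest was mitochondrial, from 200653 to 200779, with a −log10 p of 86.8. It was followed by a chromosome 1 peak from 8844253 to 8844380 with 59.3, a chromosome 4 peak from 32688822 to 32688928 with 55.2, a chloroplast peak from 6546 to 6680 with 54.0, which lay within 500 bp of a peak in another list, and a chromosome 7 peak from 11604543 to 11604672 with 53.1.

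Peaks in 1 list only lay close together in places in each list. Windows of 100 kb with 5 or more of them numbered 14 in 93-11, 6 in LYP9 and 10 in PA64s, with at most 8, 6 and 13 such peaks in a window. Whether they gathered beyond the density of all peaks was not tested. Some windows were dense in all lists, such as chromosome 8 from 7000001 to 7100000, with 26, 25 and 14 peaks in 93-11, LYP9 and PA64s. In PA64s, 3 stretches of 200 kb stood out and were chosen after their values were seen. Between 2.7 and 2.9 Mb of chromosome 9, PA64s had 27 peaks, 26 of them in that list alone, where 93-11 had 5 and LYP9 had 3. Between 16.8 and 17 Mb of chromosome 1, 25 of the 37 PA64s peaks were in that list alone, beside 23 peaks in 93-11 and 26 in LYP9. Between 11.9 and 12.1 Mb of chromosome 12, 19 of the 29 PA64s peaks were in that list alone, beside 10 in 93-11 and 12 in LYP9. Together the stretches held 70 of the 667 nuclear PA64s-only peaks, or 10.5%, and the other 597 lay elsewhere.

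LYP9 carries a nuclear genome from each parent, and the comparison of the hybrid with its parents asked where its peaks were also found. Of the 3628 LYP9 peaks, 1514 (41.7%, 95% interval 40.1 to 43.4) were found in both parents and 1090 (30.04%, 28.6 to 31.6) in 93-11 alone. Only 204 (5.62%, 4.90 to 6.42) were found in PA64s alone, and 820 (22.6%, 21.2 to 24.0) in neither. On the nuclear chromosomes the numbers were 1421, 1087, 162 and 819 of 3489 peaks.

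Seen from the parents, peaks that both shared were nearly always present in the hybrid. LYP9 had a peak at 91.9% of the 93-11 peaks that PA64s also had (1517 of 1650). Peaks of 1 parent absent from the other recurred less often and unequally. Of 2427 peaks in 93-11 and not in PA64s, 1079 were found in LYP9 (44.5%, 42.5 to 46.5). Of 883 peaks in PA64s and not in 93-11, 202 were found in LYP9 (22.9%, 20.1 to 25.8). The odds ratio was 2.70 (Fisher's exact test over peaks, two-sided p = 7.8e-31). On the nuclear chromosomes, a restriction chosen after the data were seen, the shares were 44.5% and 19.5%, with an odds ratio of 3.30 (Fisher's exact test, p = 1.5e-39). This compares the peaks of 3 libraries and not the cultivars, since each parent had 1 library.

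The shares were also taken by class of score, although scores of libraries with different tag numbers are not on the same footing. For nuclear peaks with −log10 p below 10, 21.6% of 93-11 peaks absent from PA64s and 14.3% of PA64s peaks absent from 93-11 were found in LYP9. From 10 to 20 the shares were 49.4% and 23.5%. From 20 to 40 they were 88.5% of 314 peaks and 18.5% of 65, and from 40 upwards 96.3% of 54 and 58.3% of 24. Taking all nuclear peaks of at least 20, 330 of 368 of the 93-11 and 26 of 89 of the PA64s peaks were found in LYP9. A further count left out 100 kb windows that held 5 or more peaks of 1 parent absent from the other. The shares were then 208 of 235 (88.5%) for 93-11 and 12 of 33 (36.4%) for PA64s.

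**Figure D3:**
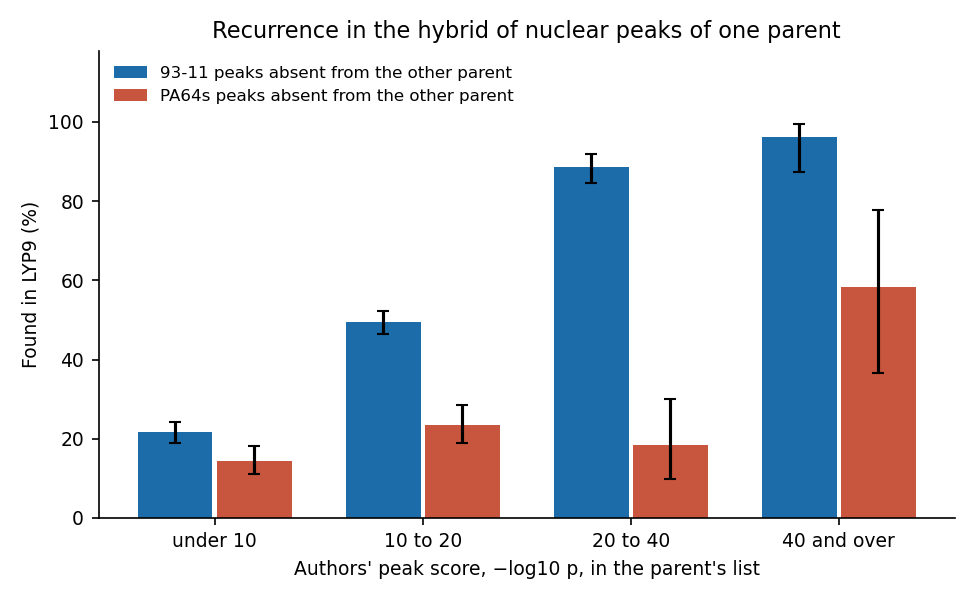
Percent of nuclear peaks of 1 parent, absent from the other parent, that overlap a LYP9 peak, by class of the authors' −log10 p in the parent's list; bars show shares with exact 95% binomial intervals. From 20 to 40 the share is 88.5% for 93-11 and 18.5% for PA64s peaks.

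The organelle sequences were compared in the same way. All 25 chloroplast peaks of LYP9 overlapped a PA64s peak, and 2 of them also overlapped a 93-11 peak. The remaining 23 were found in PA64s alone. 93-11 had no chloroplast peak outside those present in all lists, so recurrence of 93-11 peaks absent from PA64s could not be measured there. At the 2 chloroplast sites present in all lists, with summits in 93-11 at 49279 and 56219, pileups were 52 and 55 tags in 93-11, 51 and 59 in LYP9, and 82 and 69 in PA64s. Summits of paired LYP9 and PA64s chloroplast peaks lay at most 9 bp apart, and the pileup was higher in PA64s at 25 of 25 sites, by a median factor of 2.62. The pileups are unscaled, and the LYP9 library held 0.843 times as many tags as that of PA64s. Of the 114 mitochondrial LYP9 peaks, 91 were found in both parents, 19 in PA64s alone and 3 in 93-11 alone. Of the mitochondrial peaks of 1 parent absent from the other, 3 of 7 in 93-11 and 17 of 28 in PA64s recurred in LYP9, with an odds ratio of 0.485 that did not pass the threshold (Fisher's exact test, two-sided p = 0.43).

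**Figure D4:**
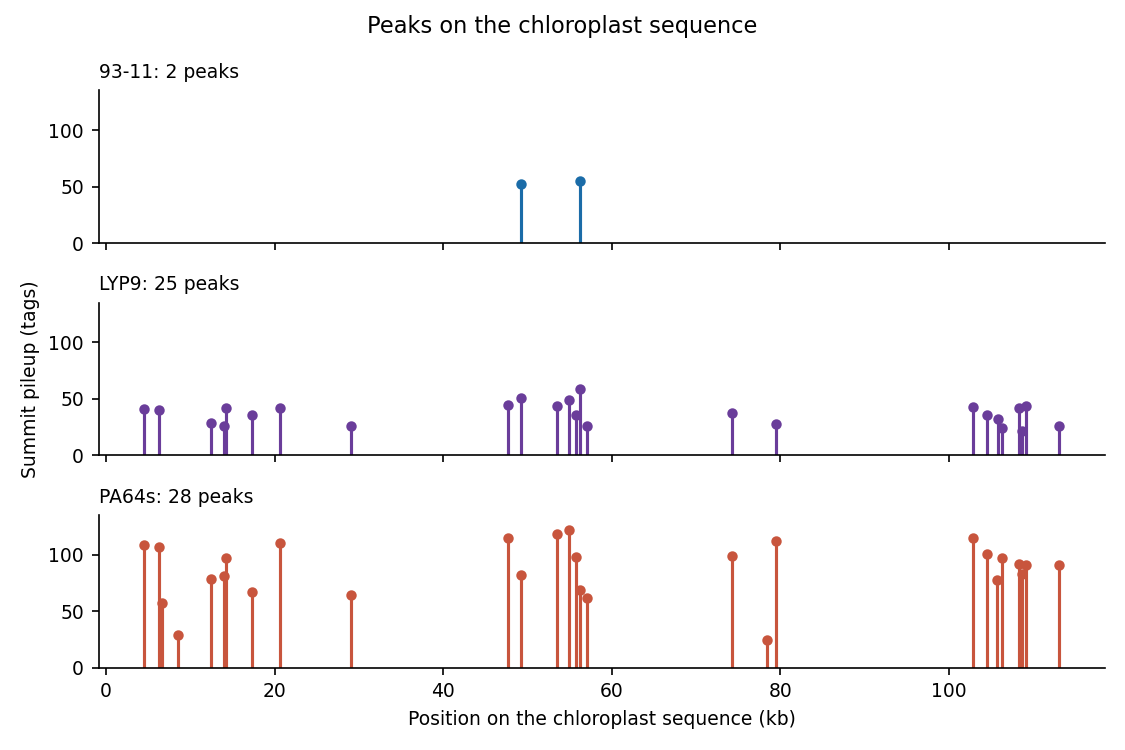
Summit pileup in tags (vertical axis) against position on the chloroplast sequence in kb (horizontal axis) for each chloroplast peak of the 3 lists. LYP9 has 25 peaks, each at a position that also has a PA64s peak, while 93-11 has 2.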

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

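All tests in this part were chosen after the results were seen, except the odds ratio with lists of equal length. The recurrence in LYP9 of peaks of 1 parent absent from the other differed between the nuclear and the organelle sequences. On the nuclear chromosomes it was 24.9 percentage points higher for such peaks of 93-11 than for those of PA64s. On the chloroplast and mitochondrial sequences pooled it was lower for 93-11, 3 of 7 against 40 of 54, a difference from the nuclear value of 56.1 percentage points (permutation of the sequence class within each parent, two-sided p = 0.0026). The pooled value mixes unlike sequences, since all 7 such peaks of 93-11 were mitochondrial and 23 of the 40 recurring PA64s peaks were on the chloroplast sequence. With mitochondrial peaks only, 3 of 7 against 17 of 28, the difference from the nuclear value was 42.8 percentage points (permutation test, p = 0.032), while the order of the parents within the mitochondrial sequence did not pass the threshold. The shares of 93-11 peaks were close, 44.5% nuclear and 42.9% organelle. Those of PA64s peaks were 19.5% nuclear, 74.1% organelle and 60.7% mitochondrial, so the differences came mainly from the PA64s peaks. Both differences rest on 7 organelle peaks of 93-11, and peaks are not replicates. The sequence classes were not matched for peak strength or density, and chance overlap within each class was not allowed for. Over all PA64s peaks the median pileup was 132 tags mitochondrial and 91.5 chloroplast, against 22 to 34 on single nuclear chromosomes. Nuclear PA64s peaks absent from 93-11 with −log10 p of at least 40 recurred in 58.3% of 24 cases. The differences can thus not be assigned to the sequence class itself.

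The chloroplast pattern, 25 peaks in LYP9 and 28 in PA64s against 2 in 93-11, may come from too few chloroplast reads in the 93-11 library. At the 2 sites present in all lists the summed pileup of 93-11 was 0.973 times that of LYP9 (95% interval 0.738 to 1.28), but these sites do not stand for the others: their ratios of PA64s over LYP9 were 1.17 and 1.61, below the range of 1.86 to 4.04 at the other 23. A cytoplasm that LYP9 receives from its seed parent PA64s is another candidate explanation. 93-11 had no chloroplast peak of its own to test it on, and the mitochondrial odds ratio of 0.485 had an exact Fisher p of 0.43. The explanations cannot be told apart with these lists, and whether the sites differ in 5hmC was not tested.

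The nuclear pattern, in which 93-11 peaks absent from PA64s recurred more often than PA64s peaks absent from 93-11, was weighed against 3 explanations. Lower deposited scores of the latter are argued against as the whole cause by an odds ratio of 3.04 within 4 score classes (Mantel-Haenszel, 95% interval 2.498 to 3.70). Dense clusters of PA64s peaks absent from 93-11 are argued against as the whole cause too. Without the 15 windows of 100 kb that held 5 or more of them, whether or not found in LYP9, the ratio was 2.504 (2.03 to 3.09). The first ratio pools unlike classes: the shares were 21.6% against 14.3% below 10 and 88.5% against 18.5% from 20 to 40. Classes of equal score are not matched for the different tag numbers, so both ratios concern the deposited scores only. A shorter PA64s list that misses regions present in all 3 cultivars cannot be told apart from a difference between the cultivars: of the 93-11 peaks found in LYP9, 73.7% with −log10 p below 10 and 11.1% with at least 40 were absent from PA64s, a fall that misses would give but that weaker regions differing between cultivars would give too. With lists of equal length the odds ratio was 6.49, but that setting keeps the weak peaks of PA64s and removes those of the other lists, and a property of single libraries stays open as well.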

How the results depend on the processing

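No paired analysis was possible because each cultivar had 1 library. The share of each list found in each other list stayed above its shuffled mean with p = 0.001 in the permutation test under every alternative run, including shuffles within 1 Mb and each chromosome left out in turn, where for example the share of LYP9 peaks found in 93-11 ran from 71.0% to 72.5%. None of these shuffles allowed for places that attract tags through extra copies or mapping. Shared peaks had the higher score in each list under each alternative run for the score. The odds ratio for recurrence in LYP9 stayed above 1 and ranged from 2.19, without clusters of peaks of 1 parent absent from the other, to 6.49, with lists of equal length. A −log10 p at or above the pooled median of 15.35 left 2013, 1790 and 1362 peaks and 330.3, 292.9 and 219.8 kb in 93-11, LYP9 and PA64s by construction. The shares of LYP9 peaks moved with the rule for sharing and with the score. With 50% of both peaks overlapping, 35.7% were found in both parents and 28.2% in neither. Within 500 bp, 48.7% were found in both, 28.3% in 93-11 alone, 4.41% in PA64s alone and 18.6% in neither. At or above the pooled median, 55.5% were in both, 28.5% in 93-11 alone and 10.9% in neither. With lists of equal length, 51.0% were in both, 26.2% in 93-11 alone, 7.78% in PA64s alone and 15.05% in neither. Of the alternatives chosen after seeing the data, nuclear chromosomes only gave 4.64% in PA64s alone. Leaving out the clusters gave 27.2% in 93-11 alone and 25.8% in neither, and −log10 p of at least 20 gave 55% in both, 4.46% in PA64s alone and 9.92% in neither. Which step caused these moves, beyond the construction of each rule, was not tested. Among the 25 named regions, the number of lists with a peak there changed within 500 bp for 4, all of them found in 1 list only as reported, for 1 with 50% overlap and for 0 at or above the pooled median. Alternatives for gene features, transposon-related genes, gene lists, base composition and gene density were not run.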

Other observations

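All tests in this part were chosen after the results were seen. Some peaks lay close to the start of a chromosome sequence. Within the first 1 kb, 93-11 and LYP9 each had 6 peaks, on chromosomes 1, 2, 5, 6, 8 and 10, and PA64s had 4, on chromosomes 1, 6, 8 and 10. On chromosome 8 the peak began at 124, 126 and 131 in 93-11, LYP9 and PA64s, with fold enrichments of 47, 44.3 and 28.5. On chromosome 1 it began at 6, 7 and 8, with 31.6, 30.04 and 21.8.

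The 3 stretches dense in PA64s-only peaks raised the hypothesis that these peaks lie in sequence near the centromeres, which differ between rice lines. Centromere positions were taken as whole Mb from general knowledge of the rice map, since no annotation of the build was used. Within 1 Mb of these positions lay 20.2% of the PA64s-only nuclear peaks and 10.8% of the PA64s nuclear peaks found in another list. The corresponding shares were 11.98% and 10.9% in 93-11 and 12.1% and 11.2% in LYP9. The PA64s-only share was the higher on 8 of 12 chromosomes (exact sign test, two-sided p = 0.39). All 70 PA64s-only peaks of the stretches that raised the hypothesis lay near these positions. Outside the stretches the shares were 10.9% of 597 PA64s-only peaks and 9.55% of 1706 others (Fisher's exact test, two-sided p = 0.34). The excess thus rested on those stretches, and no excess beyond them was detected.

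Most peaks were shorter than the sheared fragments, with 15.1% of all 10250 at 200 bp or longer. Among the 800 peaks with a pileup of at least 80 tags, 43.5% were 200 bp or longer. Among the 532 nuclear ones it was 44.5% (95% interval 40.3 to 48.9), with 43.9% in 93-11, 46.2% in LYP9 and 43.3% in PA64s. What share enriched fragments of 200 to 300 bp would give was not measured, so such fragments stay open as the source of peak shape. MACS's d of 81 to 83 bp also equalled or nearly equalled the 81 bp tag. The shortest peaks were 83 bp in 93-11, 81 bp in LYP9 and 81 bp in PA64s, the d of each list. Tags were extended to d and not to 200 to 300 bp, so peak length is no direct measure of fragment length. Uniquely mapped reads confined to short stretches of the reference are a candidate explanation. Of all 10250 peaks, 77.7% were shorter than 2 tags (162 bp), but short weak peaks would give that too. Among peaks with a pileup of at least 80 tags this share was 47%, and 44.5% among the nuclear ones of these. Without the genome the possibilities cannot be told apart.

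The highest pileups were 165 tags in 93-11, 162 in LYP9 and 160 in PA64s. If 1 tag was kept per position and strand, a pileup cannot exceed 2 times d, which is 166, 162 and 162. The median background at mitochondrial peaks, obtained as pileup over fold, was 28.7 tags in 93-11, 18.6 in LYP9 and 39.8 in PA64s, against 2.29, 2.23 and 2.84 at nuclear peaks. At chloroplast peaks it was 2.13, 2.09 and 3.34, beside genome-wide values of 2.13, 2.09 and 2.48 computed from the tag totals. In 93-11 and LYP9 the chloroplast median equalled the genome-wide value, so the typical fold there was not taken over a separate chloroplast background.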
